A study of Drosophila melanogaster with 29 samples.

How the data were processed

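Total RNA from Drosophila S2 cells was measured on 29 Affymetrix Drosophila arrays, 14 from untreated cells (Mock) and 3 each from cells treated for 4 days with double-stranded RNA (dsRNA) against dKDM2, dRING, PC, PH or PSC. The labels state 7 micrograms of RNA per one-cycle labelling and RNA integrity numbers above 8. The deposited values are log2 signals, 1 column per array and 1 value per probe set, made by the authors with background correction and summarisation. The authors' processing notes name RMA and GCRMA without a version, an order or a role for either. The lowest value was the same on all arrays (2.27 on the log2 scale). At this floor lay 41.8% of all values, so falls that reach it are understated.

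Of 18952 probe sets, 183 control probe sets were left out of the gene tests, which left 18769. The submitted probe set annotation named exactly 1 gene for 13647 of them and several genes for 402, and 4720 were not named here and were not used. Of the probe sets naming 1 gene, 13544 were matched to the Release 6 plus ISO1 MT annotation by gene number, and 103 kept the older symbol. That annotation was used for names and for gene length (genomic span with introns) alone, and probe positions were not used here. For each of 11982 genes the probe set with the highest mean over all arrays stood for the gene. The 305 genes at the floor on all 29 arrays were left out, and 11677 genes were tested. Probe sets naming Kdm2, ph-p, ph-d, Su(z)2, Ubx, abd-A, Abd-B or lab alone were not among them, so these genes were not analysed here.

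Array medians ranged from 2.271 to 2.473 and upper quartiles from 5.618 to 7.146. Because the medians differed by more than 0.1, the arrays were quantile normalized, by a rule fixed before the data were examined. A limma model (version 3.58.1 under R 4.3.3) with 6 group means was fitted to all 29 arrays, with eBayes and an intensity trend, and each depletion was contrasted with Mock and with every other depletion. All tests were two-sided. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The words rose and fell are used of called genes alone. SD is the standard deviation over arrays and SE the standard error of the log2 fold change from limma.

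The comparisons, the test, the alternatives listed as fixed beforehand, the 23 gene lists and the rule for naming genes were chosen before the data were examined. Named genes are the RNAi targets, the 8 largest rises and the 8 largest falls per depletion among called genes whose 3 arrays lay on the same side of the Mock mean, and up to 4 called members of each gene list with the largest change (for the Hox genes, every member). For dKDM2 against another depletion they are the 5 largest differences each way. For genes called in the same direction after all 5 depletions they are the 10 largest, and for genes shared by dKDM2, dRING and PSC the 5 largest each way. From these, the text prints mainly genes whose call held with each array left out in turn, a preference set after their values were seen. A gene under several parts of the rule counts under each.

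Gene lists were tested with camera from limma at its preset correlation of 0.01, two-sided, adjusted over 115 tests of 23 lists in 5 depletions. The smallest list had 4 measured genes. Members of a list were also counted with p-values adjusted over the list alone. Camera was repeated with the correlation estimated from the data.

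Because all depletions share the Mock arrays, overlaps and correlations between depletions were set beside 20 simulated data sets in which no depletion changed a gene, beside the product expected of independent calls, and beside a count in which odd-numbered Mock arrays served one depletion and even-numbered ones the other. The simulated data hold no correlation between same-numbered arrays. On simulated data of the same size, 36% of 100 genes changed by 1 on the log2 scale were recovered and 79% of 100 genes changed by 2. Of the 120 genes called there, 5 were unchanged, and 0 of the unchanged dRING genes were called by limma. A first criterion for this check, recovery above 80% at a change of 2, was missed and was replaced by limits on bias and on false calls after the result was seen.

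The numbers in the labels were checked for pairing by correlating deviations from the group mean across 5490 genes above 4 on the log2 scale in at least 15 arrays. Of 45 correlations between same-numbered arrays of different groups, 27 exceeded 0.1, with a range of -0.196 to 0.923. They passed 0.1 for all 3 numbers between Mock, dRING, PC and PSC, where they ranged up to 0.923, and between dKDM2 and PH (0.332, 0.146 and 0.598), but not between Mock and dKDM2 (0.0607, -0.11 and -0.0462) or Mock and PH (0.13, 0.0515 and 0.152). A fit with the replicate number as a block, on Mock 1 to 3 and the depletions, was therefore run beside the fit without it.

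Alternatives fixed beforehand were the mean over a gene's probe sets, every probe set on its own, a filter keeping the 6209 genes above the array median in at least 3 arrays, median centring, no intensity trend, array weights, fits of only the arrays compared, Mock 1 to 7, Mock 8 to 14, the replicate block, a call of at least 2-fold, and leaving out each array in turn. Deposited values without quantile normalization, technical covariates (hybridization control level and actin 5-prime minus 3-prime difference), replicates 1 and 2 only, and Mock 1 to 3 were added after the data were seen. Technical measures of the groups were compared by exact permutation tests, two-sided, over 680 arrangements and adjusted over 15 tests. They were the means of 9 hybridization control probe sets and of 12 poly-A spike probe sets, on deposited values, and the actin 5-prime minus 3-prime difference.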

Results

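S2 cells, a Drosophila line with features of embryonic blood cells, were depleted by RNA interference of 1 of 5 chromatin proteins, and transcripts were measured on arrays. The proteins dRING (gene Sce), PC, PH and PSC are subunits of Polycomb repressive complex PRC1, which helps keep developmental genes silent. The protein dKDM2 is a histone demethylase, and the study's title places it in Polycomb silencing. There were 14 arrays of untreated cells (Mock) and 3 arrays of each depletion. The labels call the arrays biological replicates without naming cultures, so p-values measure the spread between these arrays, whatever its source. Replicates 1 and 2 correlated more closely (r = 0.997 in Mock, 0.995 in dRING, 0.997 in PC and 0.994 on the arrays labelled PSC) than replicates 1 and 3 (0.963, 0.914, 0.916 and 0.906). Mock cells were untreated, so exposure to dsRNA is common to all 5 depletions. The 3 arrays per depletion limit the precision. Genes are given with the fold between the group means, the log2 fold change over Mock, its SE and the limma adjusted p, in this order.

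The RNAi target genes were examined first, as a check of the labels. Sce stood at 8.04 ± 0.47 (SD, n = 14) in Mock on the log2 scale and at 3.63 ± 0.88 (n = 3) after dRING depletion, and fell by 4.41 (SE 0.40, 21.2-fold, limma adjusted p = 1.24e-07). Pc stood at 6.60 ± 0.62 in Mock and at 4.39 ± 0.64 after PC depletion, and fell by 2.21 (SE 0.42, 4.63-fold, limma adjusted p = 0.00206). Psc went against its label. It stood at 6.77 ± 0.62 in Mock and at 9.13 ± 0.42 on the 3 arrays labelled PSC, and rose 5.13-fold there (log2 fold change 2.36, SE 0.31, limma adjusted p = 5.02e-06). Every array labelled PSC (8.67 to 9.51) lay above every Mock array (5.84 to 7.98). Psc rose after each of the other depletions too, to 10.24 ± 0.07 after dKDM2, 9.32 ± 0.19 after dRING, 9.54 ± 0.23 after PC and 11.23 ± 0.12 after PH depletion. The depletion stated for the arrays labelled PSC was therefore not seen at the transcript, and every direction given for these arrays rests on the label. Kdm2, ph-p and ph-d were not analysed here, so the dKDM2 and PH labels were not checked by a target.

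**Figure D1:**
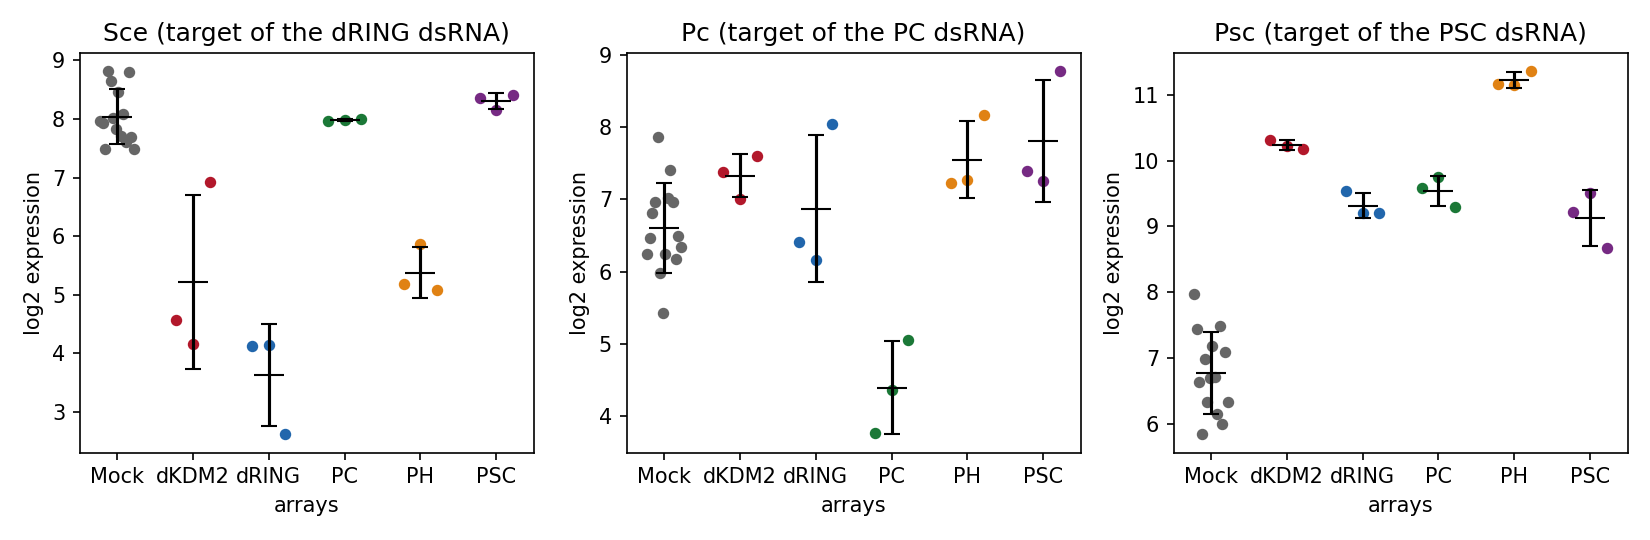
Log2 expression of Sce, Pc and Psc on each array (points) by group, with the mean and SD (lines). Sce is lowest on the dRING arrays (2.62 to 4.15), Pc on the PC arrays (3.76 to 5.05), and Psc is higher on the arrays labelled PSC (8.67 to 9.51) than on the Mock arrays (5.84 to 7.98), against the label.

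Sce fell on other arrays as well. It stood at 5.22 ± 1.49 (4.17 to 6.92) on the dKDM2 arrays and at 5.38 ± 0.43 on the PH arrays, 7.03-fold (log2 fold change -2.81, SE 0.40, limma adjusted p = 4.91e-06) and 6.31-fold (-2.66, SE 0.40, 1.01e-05) under Mock. It was 7.98 ± 0.01 after PC depletion and 8.31 ± 0.14 on the arrays labelled PSC.

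The dKDM2 and PH arrays also differed from Mock in controls added in the laboratory. Hybridization controls averaged 10.95 ± 0.58 in Mock (9.98 to 11.99), 12.49 ± 0.65 on the dKDM2 arrays and 12.97 ± 0.41 on the PH arrays (exact permutation tests, two-sided, adjusted p = 0.0110 and 0.00735). Poly-A spikes, added to the RNA before labelling, averaged 5.30 ± 1.16 in Mock, 9.01 ± 1.13 on the dKDM2 arrays and 10.22 ± 0.27 on the PH arrays (adjusted p = 0.00735 for both, from a raw exact permutation p of 0.00147, the smallest that 680 arrangements can give). On the dRING, PC and PSC arrays the hybridization controls averaged 10.64, 10.64 and 10.56 and the poly-A spikes 4.80, 4.84 and 4.40, and no difference from Mock was called (adjusted p from 0.403 to 0.589, exact permutation). The actin 5-prime minus 3-prime difference averaged -1.70 ± 1.02 in Mock, -2.90 ± 0.44 on the dKDM2 and -3.13 ± 1.07 on the PH arrays, with no group called (adjusted p from 0.132 to 0.799, exact permutation).

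**Figure D2:**
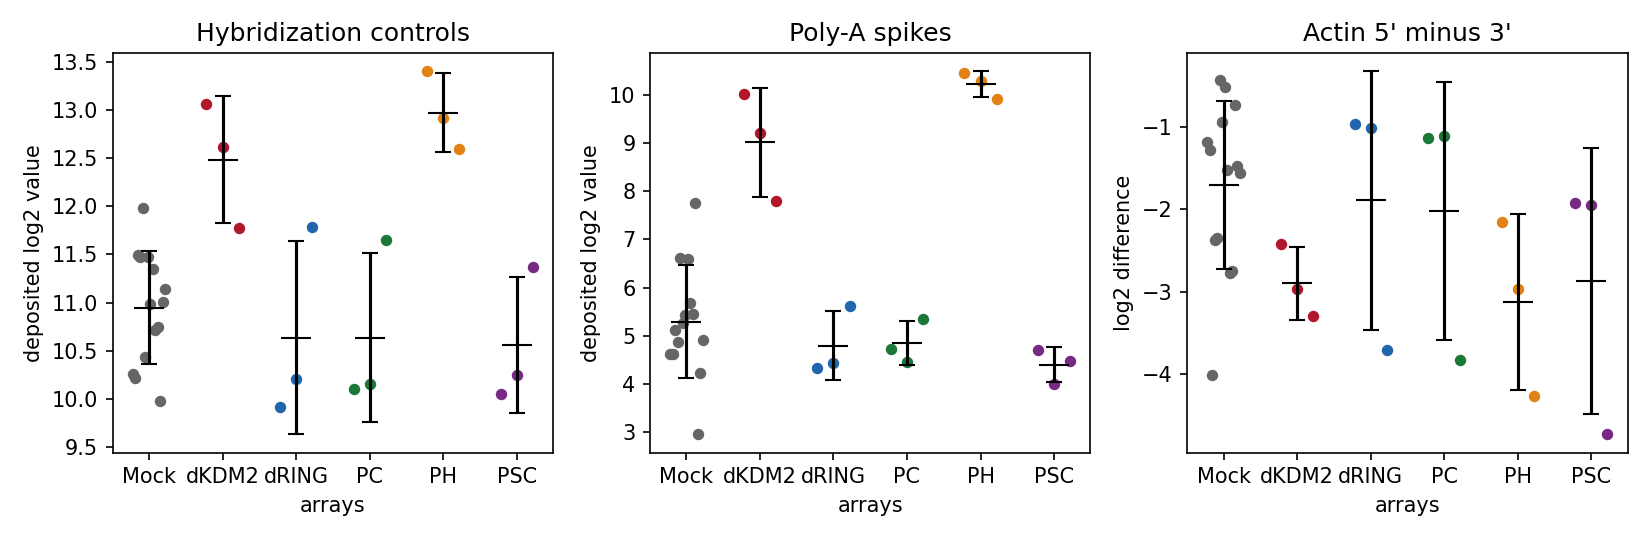
Hybridization controls, poly-A spikes (deposited log2 values) and the actin 5-prime minus 3-prime difference (log2) on each array (points) by group, with the mean and SD (lines). All 3 PH arrays lie above all 14 Mock arrays in hybridization controls (12.59 to 13.40 against 9.98 to 11.99) and in poly-A spikes (9.92 to 10.45 against 2.95 to 7.76).

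Of 11677 genes tested by limma, 3868 changed after dKDM2 depletion (2147 higher, 1721 lower), 324 after dRING (238 higher, 86 lower), 530 after PC (388 higher, 142 lower), 4080 after PH (2284 higher, 1796 lower) and 1927 on the arrays labelled PSC (1167 higher, 760 lower). The higher share for dKDM2 and PH depended on the scaling of the arrays and on the Mock arrays used. It was 55.5% for dKDM2, against 45.7% with deposited values (1914 higher, 2272 lower), 38.6% with median centring (1512 higher, 2409 lower) and 49.8% with Mock 1 to 3 alone (1339 higher, 1349 lower). For PH it was 56.0%, against 47.9% (2348 higher, 2559 lower), 35.7% (1570 higher, 2830 lower) and 49.5% (1496 higher, 1529 lower). The replicate block, a fit that also holds Mock 1 to 3 alone, gave 48.3% (1606 higher, 1716 lower) and 47.7% (1735 higher, 1900 lower). Where calls ended in it, the fewer Mock arrays may be the cause and not the block. Of the 324 dRING and 530 PC calls, 116 and 237 were also called in the same direction with the block, and 69 and 159 with the same Mock arrays, 1 to 3, and no block. The higher share for dRING was 73.5%, and 55.6% with Mock 1 to 3 (85 higher, 68 lower) and 61.3% when the block was added. Without dRING replicate 3 the dRING count was 178, and without PC replicate 3 the PC count was 322. No other array left out of these 5 counts moved one by more than 1.5 times. Transcript changes also followed gene length: across 5539 expressed genes, which are not independent replicates, longer genes had higher log2 fold changes (Spearman correlation 0.562 for dKDM2, 0.535 for dRING, 0.508 for PC, 0.480 for PH and 0.547 on the arrays labelled PSC). With the replicate block the correlations were lower (0.435, 0.308, 0.255, 0.332 and 0.365).

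**Figure D3:**
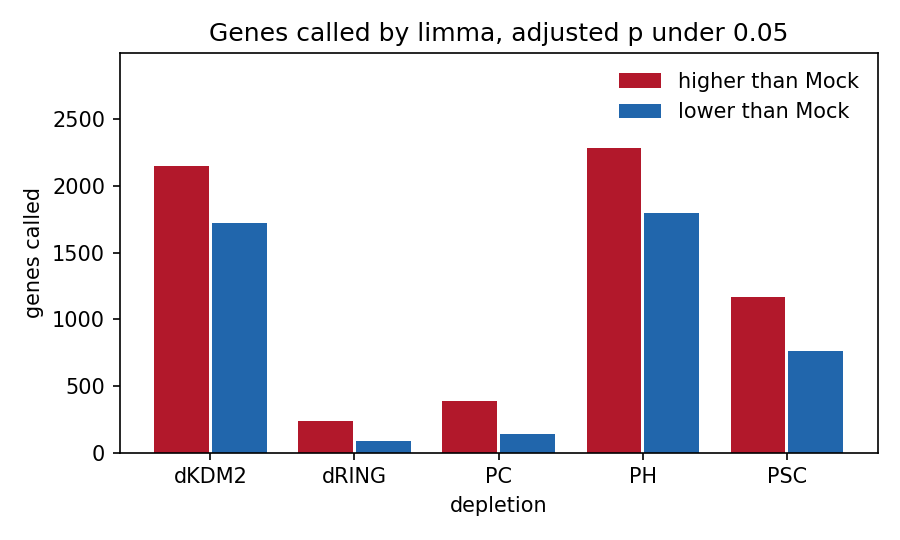
Genes called by limma at an adjusted p under 0.05 in each depletion against Mock, of 11677 genes tested, higher (red) and lower (blue). Bars reach 2147 and 1721 for dKDM2, 238 and 86 for dRING, 388 and 142 for PC, 2284 and 1796 for PH, and 1167 and 760 for the arrays labelled PSC, where the target Psc went against the label; with median centring fewer genes were higher than lower after dKDM2 (1512 and 2409) and PH depletion (1570 and 2830).

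The comparison of dKDM2 with Mock asks which genes depend on this demethylase. The largest rises included Cont, a cell adhesion protein of septate junctions (14.2-fold, log2 fold change 3.82, SE 0.54, limma adjusted p = 5.46e-06), ct, the homeodomain protein Cut (13.8-fold, 3.78, SE 0.61, 2.56e-05), and the multidrug transporter gene Mdr49 (13.2-fold, 3.72, SE 0.64, 6.38e-05). Among the next were CG11122 (13.0-fold, 3.70, SE 0.31, 4.59e-09) and the zinc finger genes sov (12.5-fold, 3.65, SE 0.37, 5.73e-08) and mld (12.2-fold, 3.61, SE 0.33, 1.19e-08). The largest falls were of regucalcin, a calcium-binding protein (37.0-fold, -5.21, SE 0.67, limma adjusted p = 1.41e-06), Dpck, a kinase of coenzyme A synthesis (28.8-fold, -4.85, SE 0.36, 4.27e-10), Marc (27.5-fold, -4.78, SE 0.35, 3.81e-10), SamDC, an enzyme of polyamine synthesis (27.4-fold, -4.78, SE 0.54, 2.54e-07), and trsn, which encodes translin (26.7-fold, -4.74, SE 0.42, 8.38e-09).

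Among Polycomb group genes after dKDM2 depletion, 9 of 15 measured rose and 2 fell, with the same counts adjusted over the list alone. Psc (11.1-fold, log2 fold change 3.47, SE 0.31, limma adjusted p = 8.68e-09), Pcl (7.32-fold, 2.87, SE 0.37, 1.25e-06) and Jarid2 (4.88-fold, 2.29, SE 0.25, 1.25e-07) rose, the last 2 encoding partners of the complex PRC2. With deposited values 6 rose and 4 fell, and with median centring 6 rose and 4 fell. The list was higher by camera (adjusted p = 0.00321, median log2 fold change 0.87), with an adjusted p = 0.245 with an estimated correlation. Its adjusted p ranged from 0.00188 to 0.277 over the other alternatives, and deposited values (0.277) and median centring (0.248) ended the call. Among Trithorax group genes, which oppose Polycomb silencing, 7 of 14 rose and 4 fell, the same adjusted over the list alone, with no call by camera (adjusted p = 0.204) except with technical covariates (0.0487, range over 6 alternatives 0.0487 to 0.613). The Mediator genes kto (7.41-fold, 2.89, SE 0.37, 1.41e-06) and skd (6.15-fold, 2.62, SE 0.26, 3.59e-08) rose, and the demethylase gene Utx fell (8.10-fold, -3.02, SE 0.59, limma adjusted p = 0.000266). Of 4 Hox genes measured, Dfd, at the floor on 13 of 14 Mock arrays, alone was called, higher by at least 0.65 and not without dKDM2 replicate 2, and pb, Scr and Antp were not called. Of 79 developmental regulators bound by Polycomb proteins, 9 rose, beside 2147 of all 11677 genes, and 1 fell (1 and 0 adjusted over the list alone). Camera gave no call (adjusted p = 0.466), but calls upward with deposited values and median centring (0.0209 and 0.0274, range over 6 alternatives 0.0209 to 0.868). With the replicate block 1 rose and 2 fell, without a call by camera (0.72).

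Genes of mitochondrial ribosomal proteins were lower after dKDM2 depletion, with 1 of 69 called higher and 50 called lower (2 and 55 adjusted over the list alone). mRpL36 (10.3-fold, log2 fold change -3.36, SE 0.35, limma adjusted p = 8.73e-08), mRpL2 (-3.29), mRpS18C (-3.27) and mRpL23 (-3.09) fell most. The list was lower by camera (adjusted p = 5.63e-18, median -1.45, over its other alternatives 2.12e-22 to 5.04e-11), with an adjusted p = 0.17 with an estimated correlation. Random lists matched on gene length and Mock level had a median of -1.41, and with the replicate block the list had -1.30 and the random lists -1.10. Of 42 cytosolic ribosomal protein genes 4 rose and 9 fell, the same adjusted over the list alone, but 2 and 12 with deposited values and 2 and 14 with median centring. RpS29 fell by 1.66 (SE 0.17, limma adjusted p = 4.75e-08), with no call by camera (adjusted p = 0.401), though one with deposited values (0.0401) and median centring (0.0274, range over 6 alternatives 0.0274 to 0.739). Of 26 cell cycle genes 6 rose and 8 fell, the same adjusted over the list alone, but 2 and 12 with deposited values, 2 and 14 with median centring and 2 and 9 with the block. The primase gene Prim1 (12.9-fold, -3.69, SE 0.46, 1.07e-06) and PCNA (4.28-fold, -2.10, SE 0.33, 1.77e-05) fell, and Cdc6, which licenses replication origins, rose (7.08-fold, 2.82, SE 0.33, limma adjusted p = 3.6e-07). Camera gave no call for this list (adjusted p = 0.412), but calls downward with deposited values (0.0126) and median centring (0.0236, range over 6 alternatives 0.0126 to 0.909).

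The comparison of dRING with Mock asks which genes depend on the ubiquitin ligase shared by PRC1 and the complex of dKDM2. Esp, a putative sulfate transporter gene (25.5-fold, log2 fold change 4.67, SE 0.79, limma adjusted p = 0.00114), and the secreted growth factor genes Idgf2 (18.3-fold, 4.20, SE 0.49, 1.04e-05) and Idgf1 (9.86-fold, 3.30, SE 0.19, 1.77e-11) were among the largest rises. The Toll family receptor gene Tollo (7.07-fold, 2.82, SE 0.43, 0.000529), Psc (5.83-fold, 2.54, SE 0.31, 1.67e-05) and the homeodomain gene cad (2.49, SE 0.29, 1.04e-05) rose too. The Toll family gene 18w rose 11.5-fold (3.53, SE 0.55, limma adjusted p = 0.000539), a call that ended with the replicate block. After Sce itself, large falls included Ect3, a galactosidase gene (10.3-fold, -3.36, SE 0.64, limma adjusted p = 0.00461), regucalcin (8.86-fold, -3.15, SE 0.67, 0.0106), nemy (8.24-fold, -3.04, SE 0.47, 0.000529), the prefoldin gene Pfdn4 (7.32-fold, -2.87, SE 0.36, 2.41e-05) and Syn1 (-2.35, SE 0.48, 0.0079). Single arrays decided other named calls. Without dRING replicate 1, Ufsp1 (-3.11), usp (0.87) and trx (1.14) were not called, and without dRING replicate 3 neither were skd (1.17), trx or Eno (0.76). The replicate block ended the calls of usp, trx, skd and Eno.

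Of 15 Polycomb group genes, 5 rose and 1 (Sce) fell after dRING depletion, the same adjusted over the list alone, but 1 rose and 1 fell with the replicate block. The list was higher by camera (adjusted p = 0.00698, median 0.32, over its other alternatives 0.00286 to 0.0952), not without dRING replicate 3 (0.0952) nor with the filter on dim genes (0.0669), with an adjusted p = 0.252 with an estimated correlation. Of 14 Trithorax group genes 2 rose and 0 fell (5 and 0 adjusted over the list alone, 6 changed at an unadjusted p under 0.05 in limma), calls that ended with the block. This list was higher by camera (adjusted p = 0.0166), not without dRING replicate 1 (0.0625), with Mock 1 to 7 (0.123), with the filter on dim genes (0.0707) nor with the replicate block (0.938). Over its other alternatives the adjusted p ranged from 0.00189 to 0.938, and it was 0.271 with an estimated correlation. Mitochondrial ribosomal protein genes were lower (median -0.615), with 0 of 69 called higher and 2 lower, the same adjusted over the list alone, and 25 changed at an unadjusted p under 0.05 in limma. These 2 calls ended with the replicate block, with deposited values and with median centring. Random lists matched on gene length and Mock level had a median of -0.698, and with the block the list had -0.195 and the random lists -0.292. The camera test gave an adjusted p = 6.77e-11 (over its other alternatives 6.61e-14 to 0.0148) and an adjusted p = 0.252 with an estimated correlation. Of 9 glycolysis genes, Eno alone was called, higher (3 higher adjusted over the list alone), but with the replicate block no gene of the list rose and 1 fell. The list was higher by camera (adjusted p = 0.00794, over its other alternatives 0.00508 to 0.304), not with the replicate block (0.304) nor with the filter on dim genes (0.0623), with an adjusted p = 0.19 with an estimated correlation. Of 79 developmental regulators 4 rose and 0 fell (5 and 0 adjusted over the list alone, 14 changed at an unadjusted p under 0.05 in limma), without a call by camera (adjusted p = 0.111) except with the filter on dim genes (0.047, range over 6 alternatives 0.047 to 0.418). With the block 1 rose. Of 26 cell cycle genes Cdc6 alone rose (1.37), and not without any 1 of the 3 dRING arrays, with deposited values or with median centring (2 higher adjusted over the list alone).

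The comparison of PC with Mock asks which genes depend on the subunit of PRC1 that binds methylated histone H3. Idgf1 rose 98.7-fold (log2 fold change 6.63, SE 0.19, limma adjusted p = 3.28e-18), and Idgf2 (19.8-fold, 4.31, SE 0.49, 3.69e-06), Esp (14.0-fold, 3.80, SE 0.79, 0.00451), cad (13.4-fold, 3.74, SE 0.29, 6.24e-09) and the segmentation gene gsb (12.0-fold, 3.58, SE 0.67, 0.00188) rose too. The aquaporin gene Prip (9.23-fold, 3.21, SE 0.23, 2.56e-09), Tollo (9.22-fold, 3.21, SE 0.43, 4.67e-05) and Psc (6.81-fold, 2.77, SE 0.31, 2.8e-06) followed. Large falls included nemy, a cytochrome b561 gene (18.3-fold, -4.19, SE 0.47, limma adjusted p = 3.06e-06), Ect3 (8.58-fold, -3.10, SE 0.64, 0.00475), Lime (6.96-fold, -2.80, SE 0.52, 0.00188), Kal1 (6.78-fold, -2.76, SE 0.44, 0.000384) and dmGlut (6.16-fold, -2.62, SE 0.53, 0.00344). Regucalcin (-2.88) was not called without PC replicate 2 or 3, nor Ac78C (3.42) without PC replicate 1 or 3. Of blood cell markers, Hml, a clotting protein gene of plasmatocytes (3.00-fold, 1.58, SE 0.14, limma adjusted p = 6.48e-08), and peb, a zinc finger gene (1.88-fold, 0.91, SE 0.10, 2.74e-06), rose.

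Of 15 Polycomb group genes 4 rose and 1 (Pc) fell after PC depletion (6 and 1 adjusted over the list alone), but 1 rose and 1 fell with the replicate block. The list was higher by camera (adjusted p = 0.00321, median 0.366, over its other alternatives 0.000878 to 0.0956), not without PC replicate 3 (0.0956), with an adjusted p = 0.245 with an estimated correlation. Of 14 Trithorax group genes 2 rose and 0 fell (4 and 0 adjusted over the list alone, 6 changed at an unadjusted p under 0.05 in limma), calls that ended with the block, with no call by camera (adjusted p = 0.129) except with Mock 8 to 14 (0.0138, range over 6 alternatives 0.0138 to 0.895). Of 79 developmental regulators 4 rose and 0 fell, the same adjusted over the list alone, and 15 changed at an unadjusted p under 0.05 in limma. Camera gave no call (adjusted p = 0.0667) except with technical covariates (0.0482) and the filter on dim genes (0.0116, range over 6 alternatives 0.0116 to 0.418). With the block 2 rose. Of 69 mitochondrial ribosomal protein genes 0 rose and 2 fell (0 and 0 adjusted over the list alone, 25 changed at an unadjusted p under 0.05 in limma). That list was lower by camera (adjusted p = 4.8e-09, median -0.652, over its other alternatives 3.31e-12 to 0.0887), not with the replicate block (0.0887), with an adjusted p = 0.271 with an estimated correlation. Random lists matched on gene length and Mock level had a median of -0.644. With the block, which ended the 2 calls, the list had -0.165 and the random lists -0.26.

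The comparison of PH with Mock asks which genes depend on the PRC1 subunit Polyhomeotic. The transcription factor gene rib rose at least 73.8-fold (log2 fold change 6.21, SE 0.06, limma adjusted p = 1.36e-29). This is a lower bound, since rib was at the floor on 12 of 14 Mock arrays, where the spread behind the SE is not measured. noc, a zinc finger gene at the floor on all 14 Mock arrays, rose at least 56.0-fold (5.81), again a lower bound. CG9733 (62.6-fold, 5.97, SE 0.97, 3.21e-05), ct (32.4-fold, 5.02, SE 0.61, 5.73e-07), chinmo, a regulator of neuronal timing (28.9-fold, 4.85, SE 0.60, 8.66e-07), Mob2 (4.79, SE 0.32, 6.13e-11) and the adhesion protein gene Nrg (24.3-fold, 4.60, SE 0.52, 2.57e-07) rose too. CG7137 (-5.64, SE 0.65, limma adjusted p = 3.13e-07), Marc (40.7-fold, -5.35, SE 0.35, 4.16e-11), rept, a DNA helicase gene (32.2-fold, -5.01, SE 0.51, 5.3e-08), and the cytochrome P450 gene Cyp310a1 (-4.80, SE 0.44, 1.54e-08) were among the largest falls, as was CG7655 (-5.04). Of other list members, cad (8.74-fold, 3.13, SE 0.29, 1.65e-08), elav, a neuronal RNA-binding protein gene (7.14-fold, 2.84, SE 0.30, 7.9e-08), and peb (5.40-fold, 2.43, SE 0.10, 7.42e-15) rose. The phagocytic receptor gene eater fell 8.77-fold (-3.13, SE 0.50, limma adjusted p = 2.31e-05).

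Of 15 Polycomb group genes 8 rose and 3 fell after PH depletion (10 and 3 adjusted over the list alone), against 6 and 5 with median centring, where the median of the list turned from 0.948 to -0.139. Psc (21.9-fold, log2 fold change 4.45, SE 0.31, 9.21e-11) and Pcl (2.12, SE 0.37, limma adjusted p = 6.46e-05) rose. The list was higher by camera (adjusted p = 0.0122, over its other alternatives 0.00546 to 0.668), with an adjusted p = 0.271 with an estimated correlation, and deposited values (0.668), median centring (0.573), technical covariates (0.0709) and the filter on dim genes (0.0581) ended the call. Of 14 Trithorax group genes 7 rose and 4 fell, the same adjusted over the list alone, but 4 and 5 with median centring, 4 and 4 with deposited values and 6 and 6 with the replicate block, with a median of 0.664 that turned to -0.146 with median centring. Camera gave no call (adjusted p = 0.684). trx rose (2.19, SE 0.28, 1.39e-06) and Utx fell 14.2-fold (-3.83, SE 0.59, limma adjusted p = 1.52e-05). Of 79 developmental regulators 15 rose, beside 2284 of all 11677 genes, and 0 fell, the same adjusted over the list alone. In limma 21 had an unadjusted p under 0.05. Camera gave no call (adjusted p = 0.308), but calls upward with deposited values (0.00261) and median centring (0.000418), where 25 of 79 and 18 of 72 rose and 1 fell in each. With the block 6 rose and 2 fell, without a camera call (0.598, range over 6 alternatives 0.000418 to 0.749). Of 26 cell cycle genes 3 rose and 14 fell, the same adjusted over the list alone (1 and 19 with deposited values or median centring), among them Prim1 (21.9-fold, -4.45, SE 0.46, 7.87e-08), Mcm5 (10.6-fold, -3.41, SE 0.46, 2.88e-06) and the kinase gene aurB (-3.41). This list was lower by camera (adjusted p = 0.000974, median -0.89, over its other alternatives 1.06e-07 to 0.0571), not with technical covariates (0.0571), with an adjusted p = 0.247 with an estimated correlation. Of 69 mitochondrial ribosomal protein genes 2 rose and 49 fell (2 and 50 adjusted over the list alone), mRpL36 by 4.36 (20.6-fold, SE 0.35, limma adjusted p = 1.77e-09). The camera test gave an adjusted p = 1.48e-16 (median -1.47, over its other alternatives 6.07e-21 to 4.31e-10) and an adjusted p = 0.17 with an estimated correlation. Random lists matched on gene length and Mock level had a median of -1.23. With the replicate block the list had -1.24 and the random lists -0.93. Of 42 cytosolic ribosomal protein genes 6 rose and 12 fell, the same adjusted over the list alone, but 3 and 13 with deposited values and 2 and 19 with median centring, without a call by camera (adjusted p = 0.401), though one with median centring (0.0343, range over 6 alternatives 0.0343 to 0.838).

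The comparison of the arrays labelled PSC with Mock was meant to ask which genes depend on this PRC1 subunit, but its target went against the label. The secreted protein gene Phk-3 rose 149-fold (log2 fold change 7.22, SE 0.37, limma adjusted p = 2.43e-13). Swim (57.1-fold, 5.84, SE 0.65, 4.94e-07), CG42268 (31.9-fold, 5.00, SE 0.39, 1.07e-09), CG9452 (4.92, SE 0.21, 6e-15), the PDZ protein gene bbg (24.6-fold, 4.62, SE 0.21, 1.19e-14), the lipophorin receptor gene LpR2 (23.7-fold, 4.57, SE 0.14, 3.85e-18) and the glutamine synthetase gene Gs2 (21.2-fold, 4.40, SE 0.45, 1.14e-07) rose too. CG14629 (50.5-fold, -5.66, SE 0.31, limma adjusted p = 6.26e-13), CG4259 (-5.62, SE 0.71, 3.33e-06), arginase (arg, 38.8-fold, -5.28, SE 0.42, 1.33e-09), fat-spondin (36.0-fold, -5.17, SE 0.57, 3.71e-07), the lipid transfer protein gene Apoltp (31.6-fold, -4.98, SE 0.74, 3.07e-05) and the ornithine aminotransferase gene Oat (25.5-fold, -4.68, SE 0.30, 2.58e-11) fell. Receptor genes of plasmatocytes fell as well, eater 24.1-fold (-4.59, SE 0.50, 3.08e-07) and Sr-CI, at the floor on 1 of 3 arrays, 16.5-fold (-4.05, SE 0.78, limma adjusted p = 0.000565). Among list members, ct (7.42-fold, 2.89, SE 0.61, 0.00129), ap (2.38, SE 0.27, 6.32e-07), trx (2.22, SE 0.28, 3.39e-06) and fng, a modifier of Notch (3.07-fold, 1.62, SE 0.03, limma adjusted p = 1.97e-23) rose. AGO3, an Argonaute of the germline, rose by at least 1.31, a lower bound, since it was at the floor on 11 of 14 Mock arrays.

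Of 15 Polycomb group genes 7 rose and 0 fell on the arrays labelled PSC (9 and 0 adjusted over the list alone, 10 changed at an unadjusted p under 0.05 in limma), Psc, Jarid2 (1.38, SE 0.25) and Asx (1.36, SE 0.18) among them. The list was higher by camera (adjusted p = 0.000269, median 0.711, over its other alternatives 0.000118 to 0.0116), with an adjusted p = 0.17 with an estimated correlation. Of 14 Trithorax group genes 3 rose and 1, Trl, fell (4 and 1 adjusted over the list alone), against 2 and 2 with the replicate block, without a call by camera (adjusted p = 0.0966) except with Mock 8 to 14 (0.0198, range over 6 alternatives 0.0198 to 0.72). Of 79 developmental regulators 5 rose and 0 fell, the same adjusted over the list alone, and 5 changed at an unadjusted p under 0.05 in limma. Camera gave no call (adjusted p = 0.632) except with the filter on dim genes (0.0468, range over 6 alternatives 0.0468 to 0.72). With the block 3 rose. Of 69 mitochondrial ribosomal protein genes 0 rose and 46 fell (0 and 56 adjusted over the list alone, 57 changed at an unadjusted p under 0.05 in limma), among them mRpL20 (-2.44, SE 0.40, limma adjusted p = 8.71e-05) and mRpL42 (-2.39). The camera test gave an adjusted p = 3.29e-24 (median -1.29, over its other alternatives 1.84e-28 to 8.07e-16) and an adjusted p = 0.0957 with an estimated correlation. Lists matched on gene length and Mock level had a median of -0.823, and the lowest of 10000 of them had -1.11. With the replicate block 25 of these genes fell, and the list had -0.909 and the lowest matched list -0.839. Of 9 glycolysis genes 5 rose and 0 fell (7 and 0 adjusted over the list alone, 7 changed at an unadjusted p under 0.05 in limma), Hex-A 8.91-fold (3.16, SE 0.59, limma adjusted p = 0.000404). Camera gave an adjusted p = 0.0062 for glycolysis (over its other alternatives 0.00248 to 0.0475) and an adjusted p = 0.17 with an estimated correlation. Of 12 Notch pathway genes 5 rose and 0 fell, the same adjusted over the list alone, and 5 changed at an unadjusted p under 0.05 in limma. Camera gave an adjusted p = 0.00698 for Notch (over its other alternatives 0.00245 to 0.0707, the highest from the filter on dim genes) and an adjusted p = 0.0957 with an estimated correlation. Of 26 cell cycle genes 1 rose and 2 fell, the same adjusted over the list alone (1 and 4 with deposited values or median centring), without a call by camera (adjusted p = 0.42) except, downward, with the replicate block (0.0225, range over 6 alternatives 0.0225 to 0.808).

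The remaining results of the fixed lists were these, in the order dKDM2, dRING, PC, PH and the arrays labelled PSC, without a call by camera. Where no other count is given, the count adjusted over the list alone was the same. The Hox genes had 0 of 4 called by limma in the last 4 (0 at an unadjusted p under 0.05). Cell cycle genes had 0 of 26 called after PC depletion (5 at an unadjusted p under 0.05 in limma). Glycolysis genes rose and fell in 4 and 2 of 9 after dKDM2 depletion and in 4 and 2 after PH depletion (5 and 2, and 4 and 2, adjusted over the list alone), where Hex-A rose by 2.44 and Pgk fell by 2.08 in both, but with median centring or deposited values 1 rose and 2 fell, and 2 rose and 3 fell. After PC depletion 0 glycolysis genes were called by limma (2 at an unadjusted p under 0.05). Of 42 cytosolic ribosomal protein genes, 0 were called after dRING depletion (3 at an unadjusted p under 0.05 in limma), 1 fell after PC depletion, and 2 rose and 2 fell on the arrays labelled PSC, the same adjusted over the list alone. Of 14 ecdysone response genes 7 rose and 2 fell, 2 rose and 0 fell, 2 rose and 0 fell, 6 rose and 2 fell, and 1 rose and 1 fell (2 and 1 with deposited values or median centring), with 7 rising after PH depletion adjusted over the list alone and the other counts unchanged by it. In the fit with the replicate block 2 rose and 1 fell after dKDM2, 2 rose and 2 fell after PH, and the calls after dRING ended. The broad gene br rose after dKDM2 depletion (2.26, SE 0.27, limma adjusted p = 5.62e-07), and usp, the partner of the ecdysone receptor, after dKDM2 (2.26, SE 0.20) and PH depletion (1.76, SE 0.20).

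Signalling lists were short. Of 12 Notch pathway genes 3, 0, 0 and 6 rose and 0, 0, 1 and 0 fell in the first 4 depletions, with 1 more rising after dRING depletion adjusted over the list alone (3 changed at an unadjusted p under 0.05 in limma after dRING). The ligase gene neur (2.72, SE 0.41, limma adjusted p = 1.37e-05) and E(spl)mbeta-HLH (2.31, SE 0.24, 5.36e-08) rose after dKDM2 depletion. Of 7 JAK/STAT genes 2 rose and 1, Stat92E, fell after dKDM2 (-1.25, SE 0.23, limma adjusted p = 0.000163), against 1 and 1 with deposited values or median centring. Of these 0 were called after dRING (1 at an unadjusted p under 0.05 in limma), 1 rose after PC (dome, called with neither scaling nor without any 1 of the 3 PC arrays), 3 after PH (upd2 not called without PH replicate 2 or any 1 of the 14 Mock arrays) and 1 on the arrays labelled PSC, with 2 rising after PC adjusted over the list alone. Of 11 antimicrobial peptide genes and targets of Imd or Toll, 1 rose and 1 fell after dKDM2 (1 and 0 adjusted over the list alone, with deposited values or with median centring, and 2 falling alone with the replicate block). Limma called 0 after dRING, PC and PH (0, 1 and 3 at an unadjusted p under 0.05), though after PH 3 rose with deposited values and 1 with median centring. Of these peptide genes and targets 2 rose on the arrays labelled PSC, AttD 5.10-fold (2.35, SE 0.39, limma adjusted p = 0.000106). Of 6 genes of the RNA interference machinery, drosha alone was called, higher after dKDM2 (5.54-fold, limma adjusted p = 6.38e-06) and PH depletion (2.16), where with median centring or deposited values 1 of the 6 rose and 2 fell, and 0 were called by limma in the others (1, 0 and 1 at an unadjusted p under 0.05). Of 8 heat shock and chaperone genes 2 rose after dKDM2, 2 after PH (calls that ended with median centring) and 2 on the arrays labelled PSC, and 0 were called by limma after dRING and PC (2 and 2 at an unadjusted p under 0.05, 1 rising after PC adjusted over the list alone), while the list median after dKDM2 turned from 0.289 to -0.248 and after PH from 0.235 to -0.421 with median centring. Of 9 apoptosis genes 1 rose and 1 fell after dKDM2 (1 and 0 adjusted over the list alone), after PH and on the arrays labelled PSC, but with deposited values or median centring 1 rose and 2 fell, 4 fell and 2 fell. After dRING and PC 0 were called by limma (0 and 1 at an unadjusted p under 0.05).

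Of 12 plasmatocyte markers 2 rose and 1 fell after dKDM2, turning to 1 and 2 with median centring or deposited values and to 2 and 5 with the replicate block. Of these 0 were called by limma after dRING (2 at an unadjusted p under 0.05), 2 rose after PC, 2 rose and 3 fell after PH, and 2 rose and 4 fell on the arrays labelled PSC, the same adjusted over the list alone. With the replicate block 1 plasmatocyte marker rose and 2 fell after dRING and 2 rose and 7 fell on the arrays labelled PSC, and camera in limma called the list lower in both. The adjusted p was 0.873 and 0.401 without the block, 0.0184 and 0.00516 with it, and ranged over 6 alternatives from 0.0184 to 0.944 and from 0.00516 to 0.613 in limma. After PC depletion camera in limma called the plasmatocyte list higher with deposited values, median centring and Mock 8 to 14 (adjusted p = 0.0307, 0.0343 and 0.0271, range over 6 alternatives 0.0271 to 0.629), and not otherwise (0.0667). Of 4 crystal cell markers peb alone rose, after PC and PH (camera in limma called the list higher after PH with median centring alone, adjusted p = 0.0351, range over 5 alternatives 0.0351 to 0.524), and 0 were called by limma in the other 3 (1, 1 and 0 at an unadjusted p under 0.05, 1 rising after dRING adjusted over the list alone), though 2 rose after dKDM2 with deposited values or median centring. Of 6 lamellocyte markers 2 rose after dKDM2, 1 rose after PH and 1 fell on the arrays labelled PSC (1 higher and 2 lower adjusted over the list alone), and 0 were called by limma after dRING and PC (1 and 1 at an unadjusted p under 0.05). Of 10 neuron markers 1 rose after dKDM2, elav (5.15-fold, 2.37, SE 0.30, limma adjusted p = 1e-06), and 3 after PH, and 0 were called by limma in the others (0, 0 and 0 at an unadjusted p under 0.05). Of 7 muscle markers 1 rose on the arrays labelled PSC, not without PSC replicate 2, with the replicate block nor with deposited values. In the first 4 depletions 0 were called by limma (0, 0, 0 and 1 at an unadjusted p under 0.05), but after PH 4 of 7 rose with deposited values and 2 of 6 with median centring, and 1 rose after dKDM2 with deposited values. Of 9 germline markers 1 rose and 3 fell after dKDM2 (2 and 2 with the replicate block, 3 falling alone with deposited values or median centring). Among them 0 were called by limma after dRING (1 at an unadjusted p under 0.05, 1 falling adjusted over the list alone), 1 fell after PC (2 adjusted over the list alone), 1 rose and 3 fell after PH, and 1 rose and 1 fell on the arrays labelled PSC. Of 7 fat body markers 2 rose on the arrays labelled PSC, and 0 were called by limma in the first 4 depletions (0, 2, 1 and 0 at an unadjusted p under 0.05, 1 rising after PC adjusted over the list alone), though 1 fell after PH with deposited values or median centring. Of 10 neuroblast and glia markers 5 rose after dKDM2 (3 with deposited values or median centring), 3 after PH (2 adjusted over the list alone, 5 with deposited values) and 1 on the arrays labelled PSC (2 adjusted over the list alone), and 0 were called by limma after dRING and PC (3 and 1 at an unadjusted p under 0.05).

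Single arrays decided part of these calls. Among members named by rule, the following were no longer called by limma in at least 1 fit without an array of their depletion. After dKDM2 depletion they were bin, Ptx1, salr, RpL3, AttD, Hsp27, egr, ftz-f1, ImpL2, msn, bam, krimp, Dfd, Ald1, crq, wor and grim. After dRING depletion they were gsb, Pcl, Jarid2, trx, Cdc6, mRpS18B, usp, mRpL30, skd, caup and Eno. After PC depletion they were Pcl, kto, toy, RpS19b, mRpS11, dome, E(spl)m3-HLH, usp, NimC1, Scm, trx, mRpL30 and aub. After PH depletion they were H, Diap2, VGlut, loco, upd2, ftz-f1, cac, vkg and osk. On the arrays labelled PSC they were Pcl, gsb, dpa, RpS19b, Ald1, Rel, E(spl)mbeta-HLH, Hsc70-3, Dark, Col4a1, msn, Fbp2, neur, sls, osa, CycE, RpS5b and Eno.

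Camera called 2, 4, 2, 3 and 4 of the 23 lists after dKDM2, dRING, PC, PH and on the arrays labelled PSC. Without PC replicate 3 it called 1 list after PC depletion, and without PC replicate 2 it called 4. With an estimated correlation it called 0 lists in each depletion (4, 5, 3, 3 and 4 at an unadjusted p under 0.05).

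Direct comparisons of dKDM2 with the other depletions ask where its transcript changes differ from theirs. Against dRING, 1599 genes differed by limma (786 higher, 813 lower after dKDM2). The receptor phosphatase gene Ptp4E (log2 difference 4.35, SE 0.32, limma adjusted p = 2.59e-09), the Hedgehog co-receptor gene boi (3.81, SE 0.70, 0.000641) and Mob2 (3.43, SE 0.41, 5.11e-06) were higher after dKDM2 and Idgf2 lower (-5.39, SE 0.63, 3.39e-06). Against PC, 1532 genes differed (739 higher, 793 lower), with Mdr49 (4.15), Lime (3.73) and nemy (3.71) higher and Idgf1 110-fold lower (-6.78, SE 0.24, limma adjusted p = 6.82e-16). Against PH, 287 genes differed (144 higher, 143 lower). This count was 5 in a fit of only the arrays compared, 91 with array weights, and 165 with the filter on dim genes. It was 691 with the replicate block, 517 without dKDM2 replicate 3, 463 without PH replicate 1 and 537 without PH replicate 3. Lime (4.84, SE 0.67, limma adjusted p = 7.96e-05) and Cyp310a1 (4.27, 4.91e-05) were higher after dKDM2 than after PH, and rib (-6.17, SE 0.08, 6.51e-27) and Cadps (-4.57, 2.26e-05) lower. noc was at the floor on all 3 dKDM2 arrays and at least 56.0-fold lower than after PH (-5.81), and rib was at the floor on 1 of the 3. Against the arrays labelled PSC, where the target went against the label, 1910 genes differed (925 higher, 985 lower after dKDM2), with Apoltp (5.76, SE 0.95, 0.000132) and Esp (5.38, SE 1.01, 0.000513) higher after dKDM2 and Phk-3 (-7.50, SE 0.48, 2.8e-11) and CG9452 (-5.13, limma adjusted p = 6.22e-13) lower.

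Between the other depletions, limma called 26 genes for dRING against PC (8 higher, 18 lower after dRING), 40 with the replicate block and 1 in a fit of only the arrays compared, where 5 of the 10 splits of the 6 arrays gave as many. It called 1937 for dRING against PH (990 higher, 947 lower). It called 1881 for PC against PH (970 higher, 911 lower), 393 for dRING against the arrays labelled PSC (137 higher, 256 lower), or 911 with the replicate block, and 459 for PC against the arrays labelled PSC (176 higher, 283 lower), or 1009 with it. PH differed from the arrays labelled PSC in 2035 genes (968 higher, 1067 lower). Fits of only the arrays compared gave fewer genes for each pair. Psc was higher after PH depletion than on the arrays labelled PSC (2.10, SE 0.40, limma adjusted p = 0.000528), and its differences from these arrays after dKDM2 (1.11, adjusted p = 0.0578), dRING (0.18, adjusted p = 1) and PC depletion (0.41, adjusted p = 0.989) were not called.

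Genes called in the same direction after dKDM2 and another depletion were counted. All depletions share the Mock arrays. Only the separate-Mock counts allow for this, since simulated data without changes yield almost no calls to share. No count allows for dsRNA exposure, absent in Mock, or the gene length trend. The overlaps therefore cannot tell whether dKDM2 and the PRC1 subunits act on the same transcripts. dKDM2 and dRING shared 253 genes (187 higher, 66 lower; 5 opposite), against 56.4 expected of independent calls, 0 in simulated data without changes and 212.5 with separate Mock arrays for each. The shared genes were 78.1% of those called after dRING depletion. dKDM2 shared 395 genes with PC (293 higher, 102 lower, 9 opposite), 74.5% of those called after PC depletion, against 92.3 expected, 0 simulated and 306.5 with separate Mock arrays. It shared 2723 with PH (1333 higher, 1390 lower, 8 opposite), against 684.7, 0 and 2306, none allowing for same-numbered arrays or raised controls. With the arrays labelled PSC, whose target went against the label, it shared 1068 (574 higher, 494 lower, 67 opposite), against 326.6, 0.05 and 858. Without Mock replicate 3 they were 377 with dRING and 475 with PC. With dRING the count was 84, 117 or 97 without dRING replicate 1, 2 or 3, with PC 186, 192 or 187 without PC replicate 1, 2 or 3, and with the arrays labelled PSC 649 without PSC replicate 2.

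Log2 fold changes of dKDM2 correlated across genes, which are not independent replicates, with those of dRING (r = 0.639, covariance 0.326), PC (0.645, 0.343), PH (0.872, 0.911) and the arrays labelled PSC (0.542, 0.410). Simulated data without changes gave r from 0.175 to 0.181 and covariances from 0.0142 to 0.0148 for these pairs. dRING and PC correlated at 0.895 (covariance 0.238; simulated 0.176 and 0.0143). Same-numbered arrays of dRING and PC also correlated after their group means were taken off (r = 0.838, 0.835 and 0.923), and those of the arrays labelled PSC with them (0.694 to 0.888). The simulated values allow for the shared Mock arrays alone, so they are too low a comparison for these 3 pairs. The same holds for dKDM2 and PH (same-numbered r 0.332, 0.146 and 0.598), both with raised controls. The remaining pairs gave r = 0.528 (dRING and PH, covariance 0.275), 0.635 (dRING and the arrays labelled PSC, 0.240), 0.553 (PC and PH, 0.301), 0.594 (PC and the arrays labelled PSC, 0.234) and 0.524 (PH and the arrays labelled PSC, 0.405), against simulated r from 0.176 to 0.184.

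**Figure D4:**
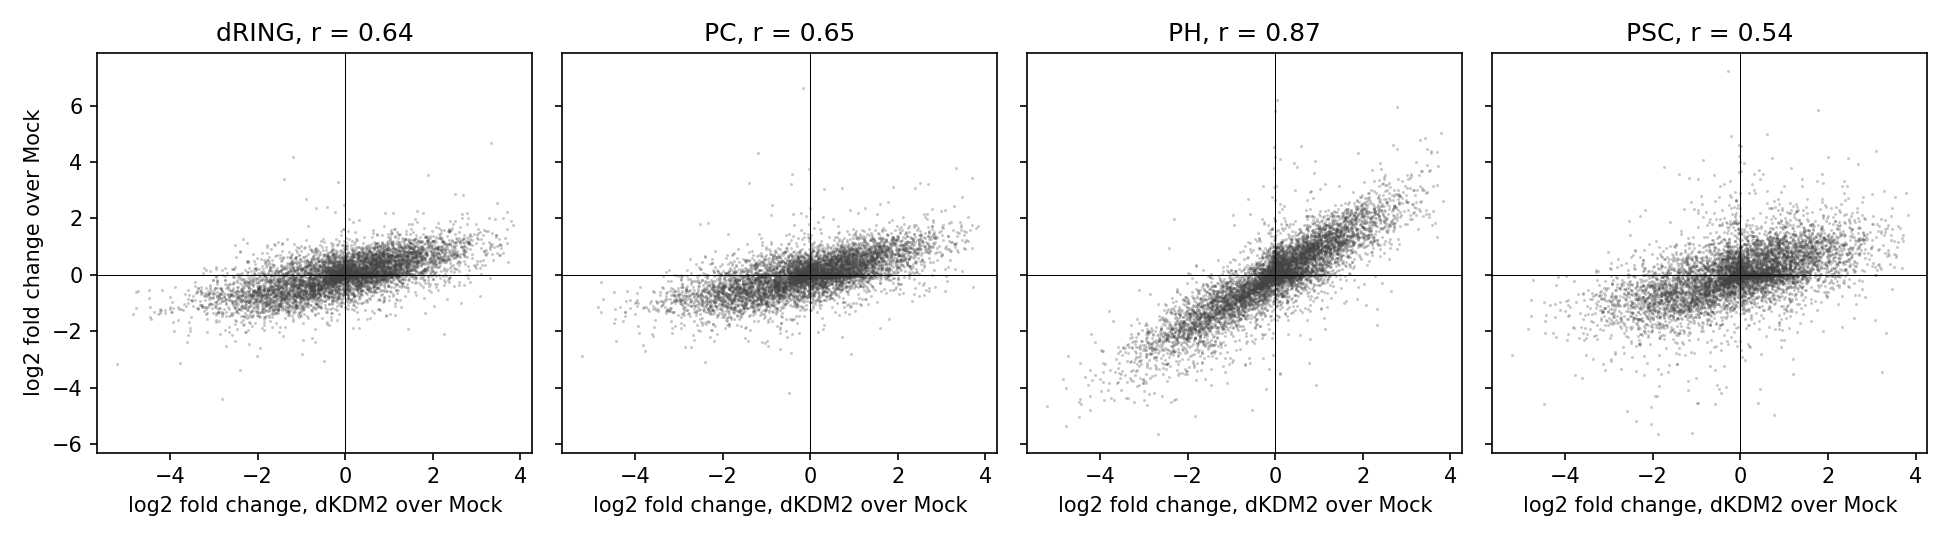
Log2 fold change over Mock of each gene (points) after dKDM2 depletion (horizontal axis) and after dRING, PC or PH depletion or on the arrays labelled PSC (vertical axis), with Pearson r across genes. r is 0.639, 0.645, 0.872 and 0.542, against 0.175 to 0.181 in simulated data without changes that share the same Mock arrays but hold no correlation of same-numbered arrays; the target of the arrays labelled PSC went against the label.

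In all 5 depletions 144 genes were called in the same direction (114 higher, 30 lower), against 0.03 expected of independent calls, which allows neither for the shared Mock arrays nor for same-numbered arrays. The count was 57, 79 or 59 without dRING replicate 1, 2 or 3 and 84, 86 or 84 without PC replicate 1, 2 or 3, and rose to 197 without Mock replicate 3. Among the largest were CG10026, which fell by 2.58, 2.12, 1.76, 4.31 and 4.84 after dKDM2, dRING, PC and PH depletion and on the arrays labelled PSC, Psc, which rose in all, and regucalcin, with a mean log2 fold change of -3.74. Regucalcin was not called after PC depletion without PC replicate 2 or 3, nor after dRING or PC depletion in fits of only the arrays compared. InR, the insulin receptor gene, rose by 3.28, 2.00, 2.46, 3.53 and 2.98, though not after dRING depletion without any 1 of its 3 arrays. Depletions of dKDM2, dRING and the arrays labelled PSC shared 193 genes (145 higher, 48 lower), and those of dRING, PC and the arrays labelled PSC shared 173 (134 higher, 39 lower), again without an expectation that allows for this.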

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

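The tests of noise near the floor, of swapped labels, of a rise of Psc transcription, and of gene length after dRING and PC depletion and on the arrays labelled PSC were chosen only after the result was seen, as were the details of the matched lists and the technical covariates.

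Controls that the gene comparisons do not use gave a signal above the level in the Mock arrays. The hybridization controls exceeded the Mock mean by 1.54 on the dKDM2 arrays and by 2.02 on the PH arrays (log2). The poly-A spikes exceeded it by 3.72 and 4.93.

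The first pattern is the many calls on the dKDM2 and PH arrays (the fewest with array weights, 2756 and 1969) and a lower Sce. Less labelled sample RNA beside the controls is a candidate explanation. The slope of each gene on the hybridization control level among the 14 Mock arrays was set beside the log2 fold changes. They correlated at r = -0.231 (dKDM2) and -0.107 (PH), where this explanation needs at least 0.3. A fit holding technical covariates shared 2628 dKDM2 and 2234 PH calls in direction (3323 and 2912 calls). Neither test used the poly-A spikes and the controls reached above the Mock range, so neither decides it. Noise near the floor was argued against, since 20.2% and 23.9% of called genes had every group mean under 5. So was a swap of labels with the dRING arrays, whose highest held Sce at -3.33 relative to the lowest Mock array. The fall of Sce lay at the 4.2 (dKDM2) and 5.08 (PH) percentiles of 1024 genes of like Mock level. As a set these genes did not fall (median 0.0618 and 0.01). Quantile normalization takes out a fall common to a signal level, so these medians cannot weigh against such a fall. A fall of the size seen for Sce was in the range of these genes for PH and, between the 1st and 5th percentile, open for dKDM2. A technical state outside the Mock range and an effect of the depletions both stay open, since the controls differ by group.

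The second pattern is Psc, which was higher on the arrays labelled PSC. A swap of labels with another depletion needs a partner low in Psc, but the lowest array of the other depletions lay 2.43 above the Mock mean (log2), so the tables argue against it. A rise of Psc transcription larger than its loss to dsRNA would put Psc lower on these arrays than in the other 4 depletions, and 1 of 4 differences was called (PH, 2.10 higher), while dKDM2, PC and dRING were higher by 1.11, 0.41 and 0.18 (SE 0.40 each) without a call, so these values neither establish nor exclude it. A wrong label without a partner and a signal of the probe set that dsRNA does not lower were not tested.

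The third pattern is the lower level of mitochondrial ribosomal protein genes, which are short, while log2 fold changes rose with gene length. Among 10000 random lists matched on gene length and Mock level, the list median lay at the 46, 87.2, 43.7 and 9.4 percentiles after dKDM2, dRING, PC and PH depletion and with the replicate block at the 9.95, 98.8, 95.3 and 5.4 percentiles, all at or above the 5th that short genes as the cause need, so gene length may account for these 4, for PH by a narrow margin. On the arrays labelled PSC the list median with the block (-0.909) lay below all 10000 matched lists (percentile 0, lowest -0.839), which argues against short genes as the whole cause there. In 40 simulated data sets with an effect of length alone, 5 fell below the 5th percentile and 0 below the 1st, and 40 of 40 did so with a shift of 0.5 added. What makes fold changes follow length, and why the list was lower on the arrays labelled PSC, whose target went against the label, was not tested.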

How the results depend on the processing

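Deposited values, technical covariates, replicates 1 and 2 only and Mock 1 to 3 were chosen after the data were seen. So were all alternatives for the pairs without dKDM2, camera with median centring and with 1 array left out, and the correlations with 1 array left out. The replicate block fit holds Mock 1 to 3. Pseudocounts do not apply to log2 values, no target gene had another probe set, and the targets of dKDM2 and PH gave no value, so these alternatives were not run. Where a value moved, the cause was not tested.

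The count after dKDM2 depletion (3868) stayed within 1.5 times under every alternative run. After dRING depletion (324) it was 520 with the filter on dim genes, 167 with median centring, 178 with deposited values, 3125 with array weights, 187 in a fit of only the arrays compared. It was 163 with Mock 1 to 7, 944 with Mock 8 to 14, 153 with Mock 1 to 3, 213 at 2-fold or more, 690 with technical covariates and 682 with replicates 1 and 2 only. After PC depletion (530) it was 3296 with array weights, 321 with Mock 1 to 7, 1048 with Mock 8 to 14, 260 with Mock 1 to 3, 821 with technical covariates and 929 with replicates 1 and 2 only. After PH depletion (4080) it was 1969 with array weights and 2645 at 2-fold or more. On the arrays labelled PSC (1927) it was 4039 with array weights and 1124 with Mock 1 to 3. Leaving out 1 array gave 178 (without dRING replicate 3) to 481 (without Mock replicate 3) after dRING and 322 (without PC replicate 3) to 620 (without Mock replicate 3) after PC depletion.

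Among differences between depletions, fits of only the arrays compared gave fewer genes: dKDM2 with dRING 815, with PC 771, with PH 5 and with PSC 987, dRING with PC 1 and with PH 1067. PC with PH had 947 and PH with PSC 990. The replicate block gave more: dKDM2 with dRING 2679, with PC 2603, with PH 691 and with PSC 2879. dRING had 40 with PC, 3046 with PH and 911 with PSC, PC with PH 2989 and with PSC 1009, and PH with PSC 3076. With replicates 1 and 2 only the counts were 4054, 4024, 1321 and 4211 for dKDM2 with dRING, PC, PH and PSC. They were 120, 4253 and 1744 for dRING with PC, PH and PSC, 4200 and 1774 for PC with PH and PSC, and 4231 for PH with PSC. Technical covariates gave 1234 for dKDM2 with PSC, 1149 for dRING with PH, 1001 for PC with PH and 987 for PH with PSC. Array weights gave 91 for dKDM2 with PH, 819 for dRING with PC, 2977 for dRING with PSC and 3168 for PC with PSC. The 287 genes between dKDM2 and PH became 438 with every probe set on its own, 165 with the filter on dim genes, 173 at 2-fold or more and 476 with deposited values, and ranged from 249 (without dKDM2 replicate 1) to 537 (without PH replicate 3).

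Genes shared in direction by dKDM2 and dRING (253) were 424 with the filter on dim genes, 115 with median centring, 121 with deposited values, 1215 with array weights, 122 with only the arrays compared. They were 123 with Mock 1 to 7, 725 with Mock 8 to 14, 109 with Mock 1 to 3, 474 with technical covariates and 506 with replicates 1 and 2 only, and ranged from 84 (without dRING replicate 1) to 377 (without Mock replicate 3). Those shared by dKDM2 and PC (395) were 1300 with array weights, 253 with only the arrays compared, 233 with Mock 1 to 7, 815 with Mock 8 to 14, 186 with Mock 1 to 3, 263 at 2-fold or more, 601 with technical covariates and 710 with replicates 1 and 2 only, and ranged from 186 (without PC replicate 1) to 475 (without Mock replicate 3). dKDM2 and PH shared 1384 with array weights. dKDM2 and PSC shared 585 with Mock 1 to 3 and 649 (without PSC replicate 2) to 1147 (without Mock replicate 2) with 1 array left out. The 144 genes shared by all 5 were 219 with the filter on dim genes, 61 with median centring, 66 with deposited values, 519 with array weights, 64 with only the arrays compared. They were 74 with Mock 1 to 7, 416 with Mock 8 to 14, 66 with Mock 1 to 3, 83 at 2-fold or more, 223 with technical covariates and 311 with replicates 1 and 2 only, and ranged from 57 (without dRING replicate 1) to 197 (without Mock replicate 3).

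Of the RNAi targets, Pc after PC depletion was no longer called with Mock 1 to 3 (log2 fold change -2.12), and Sce after dRING depletion and Psc on the arrays labelled PSC were called under every alternative run. With odd Mock arrays for one depletion and even ones for the other, r was 0.614 (dKDM2 and dRING), 0.621 (dKDM2 and PC), 0.859 (dKDM2 and PH), 0.527 (dKDM2 and PSC), 0.844 (dRING and PC), 0.603 (dRING and PSC) and 0.564 (PC and PSC), and with deposited values 0.8996 for dKDM2 and PH. Leaving out 1 array gave 0.549 to 0.667 for dKDM2 and dRING, 0.563 to 0.659 for dKDM2 and PC, 0.848 to 0.876 for dKDM2 and PH, 0.514 to 0.557 for dKDM2 and PSC, 0.831 to 0.904 for dRING and PC. It gave 0.411 to 0.574 for dRING and PH, 0.581 to 0.653 for dRING and PSC, 0.447 to 0.585 for PC and PH, 0.546 to 0.614 for PC and PSC and 0.472 to 0.542 for PH and PSC.

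Camera called 4 lists after dKDM2 depletion with deposited values and 4 with median centring (main 2). It called 2 after dRING with the filter on dim genes (main 4). After PC depletion (main 2) it called 4 with Mock 8 to 14, 1 with the replicate block, and 1 (without PC replicate 3) to 4 (without PC replicate 2) with 1 array left out. After PH depletion (main 3) it called 1 with technical covariates and 5 with median centring.

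Signs reversed in 5 results for named genes. After dKDM2 depletion salr ranged from -0.0116 (without dKDM2 replicate 1) to 0.94, and grim from -0.0021 (without dKDM2 replicate 3) to 0.38, with 0 in replicates 1 and 2 only. After PH depletion cac ranged from -0.0017 (without PH replicate 2) to 0.12, osk from -0.0025 (without PH replicate 3) to 0.058, and loco was -0.31 with median centring and -0.17 with deposited values. For sls on the arrays labelled PSC the value with deposited values was 0, without a sign.

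The 387 results for named genes kept direction and side of the threshold in 377 with the mean over the probe sets, 383 without an intensity trend, 369 with Mock 8 to 14, 348 with technical covariates, 338 with deposited values, 336 with median centring, 335 with array weights. They did so in 327 with replicates 1 and 2 only, 325 with Mock 1 to 7, 325 with only the arrays compared, 310 with the replicate block and 284 with Mock 1 to 3. Over all fits with 1 array left out, 5834 values of these results kept direction and side of the threshold. Another 300 were no longer called, 4 were reversed and 1 was newly called. 

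The replicate block called 3322, 271, 443, 3635 and 1568 genes after dKDM2, dRING, PC and PH depletion and on the arrays labelled PSC. Of the calls without it, 2621, 116, 237, 2822 and 1106 were also called in the same direction with it. With the same Mock arrays, 1 to 3, and no block these numbers were 2220, 69, 159, 2477 and 860. So fewer Mock arrays alone also ended many calls. Calls of named genes that ended numbered 76 with the block and 103 with Mock 1 to 3 and no block, so the losses cannot be put down to the block alone. The block fit added 1 call, Pc after PH depletion. The camera calls of the Trithorax group and of glycolysis after dRING and of mitochondrial ribosomal proteins after PC depletion ended in the block fit, and camera was not run with Mock 1 to 3 and no block.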

Other observations

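The tests of other splits of the arrays were chosen before the results were seen, and the comparisons of splits by array pairs, of the array numbers as sets, of gene length among Mock arrays and of the slopes in dRING, PC and the arrays labelled PSC were chosen after.

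Splits of the 17 arrays of a depletion and Mock, 100 each, tested whether chance assignment could give as many calls in a fit of these arrays alone. For dKDM2 (3522 genes, highest other split 134) and PH (3629, 258) only 1 of 100, the real split, gave as many. This argues against chance but not a technical difference. The same 1 of 100 was found for PC (358, 190) and the arrays labelled PSC (1612, 137), and 3 of 100 for dRING (187, 618). Same-numbered arrays of Mock and of dRING, PC and the arrays labelled PSC correlated (r from 0.617 to 0.84), which the 100 splits ignore. For dRING the splits of Mock 4, Mock 5 and dRING 3 (411 genes) and of Mock 5, Mock 10 and dRING 3 (618 genes) called more than the real count, 618 several times as many, which points to a structure of the samples. The replicate block gave 271 genes for dRING. The 8 splits that part all 3 same-numbered pairs are too few for a share under 0.05. Among them the highest other count was 7 for dRING, 9 for PC and 8 for the arrays labelled PSC, and the others hold Mock arrays of the pairs in place of depleted ones.

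Between 2 depletions 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real and the highest other counts were 815 and 0 for dKDM2 with dRING, 771 and 0 with PC, 5 and 0 with PH, and 987 and 0 with PSC. They were 1 and 1 for dRING with PC (5 of 10 splits gave as many), 1067 and 0 for dRING with PH, 300 and 0 for dRING with PSC, 947 and 0 for PC with PH, 399 and 1 for PC with PSC, and 990 and 0 for PH with PSC.

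Fold changes were also compared between the arrays numbered 1 and 2 and the array numbered 3, each against Mock arrays of the same numbers. Across all genes, which are not independent replicates, the sets correlated at r = 0.746 for dKDM2, 0.625 for dRING, 0.636 for PC, 0.777 for PH and 0.766 for the arrays labelled PSC. Among Mock arrays alone, the log2 differences of Mock 8 to 14 from Mock 1 to 7 had a Spearman correlation of -0.282 with gene length. Those of Mock 3 from Mock 1 and 2 had -0.013.

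The slope of each gene on the hybridization control level among the 14 Mock arrays correlated with the log2 fold changes at r = -0.53 for dRING, -0.482 for PC and -0.335 for the arrays labelled PSC. The hybridization controls of these groups lay 0.31, 0.31 and 0.39 below the Mock mean, differences that were not called, and a negative r is the sign that a technical trend would give there. With technical covariates, which were chosen after the data were seen, 690, 821 and 2053 genes were called, and 322 of 324, 504 of 530 and 1577 of 1927 calls were shared in direction. This argues against the trend as the whole cause of these calls, and a technical part of the fold changes stays open.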
